A study of Homo sapiens with 12 samples.

How the data were processed

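Gene expression was measured on 12 arrays of HK-2 cells, an immortalized line of human proximal tubule epithelial cells. The arrays fall into 4 groups of 3: cells exposed to CsA (read here as cyclosporin A, a calcineurin inhibitor that binds cyclophilins) for 12 h or 48 h, and vehicle controls at each time. Per the labels' protocols, cells were seeded the day before exposure and treated when nearly confluent, total RNA was isolated on columns, and biotinylated cRNA was hybridized to Affymetrix arrays. The labels call the replicates biological. The CsA dose and the vehicle are not given in the sources used here.

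The deposited values are log2 probe set summaries made by the authors with GCRMA, per the submitters' processing notes, which give neither version nor settings. GCRMA by its usual settings corrects background from probe sequence, normalizes quantiles between arrays and summarizes the probes of each set. Its background correction compresses dim probe sets toward a floor, so a fold change against a value near that floor is uncertain. A gene whose 3 arrays of a group all lay under a log2 value of 4 is described as near background there. No further normalization was applied before the main comparisons. No pair among the 66 pairs of arrays held identical values.

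The table held 54675 probe sets. A platform annotation gave 1 gene symbol for 41097 of them, several for 1801 and none for 11777, and symbols were checked against a RefSeq gene table by gene identifier. The build behind the platform annotation is not given in the sources used here, so no coordinates are printed. Probe sets with 1 symbol were kept when the log2 value was above 4 on at least 3 arrays, which left 20625. The probe set with the highest mean over all arrays stood for its gene, which gave 11154 genes. Other probe sets of a gene can differ from it, and those whose names end in x_at can share sequence with related genes.

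All 12 arrays entered 1 linear model with 4 groups in limma 3.58.1 (R 4.3.3), without trend or robust priors, so that all groups shared 1 estimate of the spread on 8 residual degrees of freedom. The contrasts were CsA against control at 12 h, the same at 48 h, the difference of these effects, and control at 48 h against control at 12 h. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. All adjusted p-values of single genes come from limma with this adjustment. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 35 lists within a contrast, with camera at an estimated correlation and fry beside it. Members of a list were also counted at an adjusted p computed over the list alone. The list tests of control at 48 h against 12 h were added after the data had been examined.

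The design, the lists and the rule for naming genes were fixed before the data were examined. Named genes are those with the largest changes past the threshold, separated arrays and a mean log2 value of at least 6 in the higher group. They number up to 10 in each direction for each CsA comparison, and 5 in each direction for time and for the difference, where separated arrays were not required. Up to 4 members with the smallest p in each list called by camera in a CsA contrast were added, with PPIA, PPIB, PPP3CA, RCAN1, HAVCR1, DDIT3, HSPA5 and HMOX1 always included. Any other gene named was chosen after its values were seen.

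The fit was tested on simulated data: 10 simulations of 11154 genes with 200 changed, using each gene's spread at each time. Arrays were drawn independently, so the pairing by replicate number found at 12 h and between the controls was not simulated. At 12 h, 79.6% of genes changed 2-fold were recovered and 4.49% of the calls were false. A fit of the 12 h arrays alone recovered 85.2%, with 5.56% false calls, because the wider 48 h arrays raise the shared estimate of the spread. At 48 h, 80.0% were recovered, but 33.1% of the calls were false, because the tighter 12 h arrays lower the shared estimate of the spread. A fit of the 48 h arrays alone gave 4.62% false calls there and recovered 55.2% of the 2-fold changes. The share of false calls was 9.54% for the difference and 9.50% for time. The total at 48 h, the 20 genes with the largest changes and the probe sets with no single gene name are therefore counted in both fits. So are the members past the threshold over all genes of each list described at 48 h. For the remaining lists, members that passed in the 48 h arrays alone are given. Other counts at 48 h come from the shared fit alone.

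Whether replicate numbers pair the arrays was checked from the correlation, across genes, of deviations from the group means. Arrays with the same number correlated at 0.467 to 0.577 between CsA and control at 12 h and at 0.278 to 0.325 between the controls of both times, above the minimum of 0.1 set for every pair. At 48 h not every pair exceeded it. The pairing comes from the labels' replicate numbers, and the 12 h count with the replicate number as a block was 0 genes.

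Alternatives covered the filter, the mean of all probe sets of a gene, quantile and cyclic loess normalization, trend and robust priors, array weights, a test against a 1.2-fold change, a fit of the compared groups alone, the replicate block, and leaving out each array. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. For arrays, the number of replicates limits the precision, and with 3 against 3 the smallest two-sided permutation p is 0.1. Probe sets with no single gene name were left out of the gene counts and tested separately.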

Results

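The series asks which transcripts change when a human kidney tubule cell line is exposed to CsA, a nephrotoxic immunosuppressant, for 12 h or 48 h. Each of the 4 groups held 3 arrays, and a log2 change rests on 3 arrays per group unless an array is said to be left out. Between 42.2% and 42.8% of probe sets lay above a log2 value of 4 on each array. The median SD of a gene within a group was 0.11 for CsA at 12 h, 0.10 for control at 12 h, 0.20 for CsA at 48 h and 0.15 for control at 48 h. Replicate 3 of CsA at 48 h had a median hybridization control signal of 6.95, against 9.60 to 10.95 on the other arrays. Replicate 1 of both 48 h groups had low poly-A control signals, 4.32 with CsA and 4.16 in the control, against 8.33 to 9.82 elsewhere.

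At 12 h, DNAJB9, a co-chaperone of the endoplasmic reticulum (ER), rose 1.80-fold with CsA (log2 change 0.84, SE 0.10, limma with Benjamini-Hochberg, adjusted p = 0.0464). It was the only gene of 11154 to pass. The list of ER chaperones and ER-associated degradation was shifted upward: 24 of 26 measured members had a positive change, with a median of 0.41. By camera its adjusted p was 1.85e-24, and adjusted p = 0.0591 with an estimated correlation. Apart from DNAJB9, HSPA5, the main Hsp70 chaperone of the ER, had a log2 change of 0.78 (SE 0.14, limma adjusted p = 0.699), MANF, a stress-induced secreted protein, of 0.80 (SE 0.19) and HERPUD1, part of ER-associated degradation, of 0.62 (SE 0.14). A dimmer probe set of HSPA5 gave 1.22 at 12 h and 0.31 at 48 h. Over all genes 1 member was higher, and 10 were higher when adjusted over the list alone.

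Stress and lipid lists were also shifted upward at 12 h. In the ATF4 and CHOP stress response, 20 of 24 members had a positive change, with a median of 0.20 (camera adjusted p = 1.37e-09, and adjusted p = 0.0591 with an estimated correlation). No member passed over all genes, and 6 were higher and 1 lower when adjusted over the list alone. The largest values were 1.31 (SE 0.26) for CHAC1, an enzyme that breaks down glutathione, 1.13 (SE 0.23) for SLC7A11, the cystine transporter, and 0.88 (SE 0.19) for GDF15, a stress-induced cytokine, each at a limma adjusted p of 0.731. Cholesterol synthesis and uptake had a median of 0.21 over 18 members, 16 of them positive (camera adjusted p = 1.01e-12, and adjusted p = 0.0591 with an estimated correlation). None passed over all genes, and 9 were higher when adjusted over the list alone, among members such as STARD4, a sterol carrier, with 0.53 (SE 0.15), LSS, lanosterol synthase, with 0.41 (SE 0.11) and INSIG1, a sterol sensor, with 0.38 (SE 0.10). Fatty acid synthesis had a median of 0.25 over 14 members (camera adjusted p = 5.6e-07, and adjusted p = 0.0974 with an estimated correlation). None of them passed over all genes and 1 was higher when adjusted over the list alone, with ACSS2, acetyl-CoA synthetase, at 0.67 (SE 0.21) and LPIN1, a phosphatidate phosphatase, at 0.47 (SE 0.11).

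Immediate early genes, rapidly induced regulators, had a median of 0.24 at 12 h, with 18 of 19 members positive (camera adjusted p = 5.97e-05, and adjusted p = 0.498 with an estimated correlation). None passed over all genes and 1 was higher when adjusted over the list alone. KLF4, a transcription factor, had a log2 change of 1.23 (SE 0.30, limma adjusted p = 0.866, and 0.0361 in the 12 h arrays alone with the replicate number as a block) and KLF6 of 0.42 (SE 0.18). At 48 h the log2 change was 1.61 for KLF4 and 0.60 for KLF6. The cytosolic aminoacyl-tRNA synthetases had a median of 0.11 over 15 members (camera adjusted p = 0.00527, and adjusted p = 0.498 with an estimated correlation), with AARS1 at 0.44 (SE 0.12). The NF-kB targets and cytokines had a median of 0.10 over 15 (camera adjusted p = 0.00634, and adjusted p = 0.523 with an estimated correlation), with IL6 at 0.55 (SE 0.27) and CXCL8 at 0.38 (SE 0.18). Its median was 0.0014 with dim probe sets kept and 0.06 with the mean of all probe sets, where the call held, and 0.06 with a filter at a log2 value of 6, where it ended (camera adjusted p = 0.0612). For the mitosis list the median was -0.23 and 0 of 33 members were positive (camera adjusted p = 0.0250, and adjusted p = 0.859 with an estimated correlation), with AURKB at -0.34 (SE 0.39). Oxidative phosphorylation had a median of -0.03 over 35 members (camera adjusted p = 0.0361, and adjusted p = 0.498 with an estimated correlation), with NDUFS3 at -0.21 (SE 0.08), and its call ended with the replicate number as a block within each time (camera adjusted p = 0.05002) or in the 12 h arrays with the block (0.0581). In these last 4 lists no member passed in limma, either over all genes or adjusted over the list alone. The SEs at 12 h use the spread shared with the wider 48 h arrays and no pairing. For mitosis the CsA list means by replicate were 11.40, 11.54 and 11.52, each below the control mean of its number (11.64, 11.74 and 11.76).

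No cyclophilin or calcineurin gene named beforehand passed at 12 h. The log2 change was -0.03 (SE 0.07) for PPIA, the abundant cytosolic cyclophilin, 0.24 (SE 0.13) for PPIB, the ER cyclophilin, -0.07 (SE 0.15) for PPP3CA, the calcineurin catalytic subunit, and -0.06 (SE 0.14) for RCAN1, a calcineurin-regulated inhibitor of calcineurin. DDIT3, the stress factor CHOP, had 0.70 (SE 0.26), HAVCR1, a tubular injury marker, 0.31 (SE 0.21) and HMOX1, heme oxygenase, -0.02 (SE 0.18), and none of them passed. At an unadjusted p under 0.05 there were 318 genes, 190 higher and 128 lower, and 13.04% of genes had all CsA arrays outside the range of the controls, against 10% if all arrays were independent. The 12 h arrays pair by replicate number and genes are not independent, so the share by chance is not known. The 1 call was absent with the replicate number as a block (0 genes, or 2 others in the 12 h arrays alone with the block) and with any single array left out except CsA 12 h replicate 2, where DNAJB9 had adjusted p = 0.0306. The highest such p was 0.441. Leaving out 1 array also ended list calls: mitosis without CsA 12 h replicate 1 (median -0.20) or 2 (-0.23) or control replicate 3 (-0.21), NF-kB targets without CsA replicate 1 (0.11), oxidative phosphorylation without CsA replicate 1 (-0.03) or control replicate 1 (-0.03) or 3 (-0.05), and the tRNA synthetases without CsA replicate 3 (0.08) or control replicate 2 (0.08), while medians moved for NF-kB targets without CsA replicate 3 (0.04) or control replicate 1 (0.20), immediate early genes without control replicate 2 (0.14) and fatty acid synthesis without CsA replicate 2 (0.16).

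**Figure D1:**
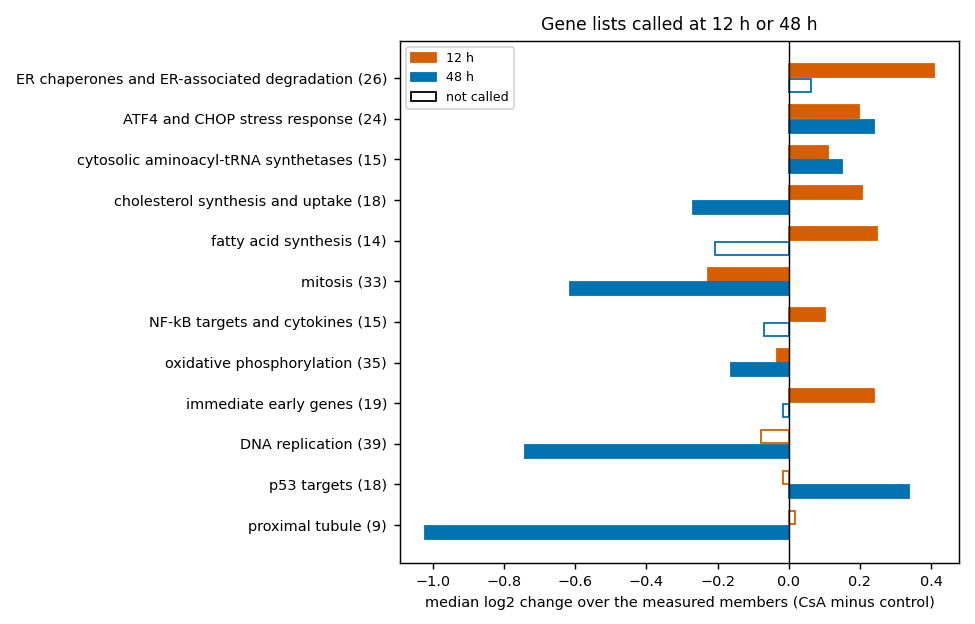
Median log2 change with CsA over the measured members of each gene list called by camera at the preset correlation at 12 h (orange) or 48 h (blue), with the number of members in parentheses; open bars were not called at that time. The ER chaperone list had a median of 0.41 at 12 h and 0.06 at 48 h, and the DNA replication list -0.08 and -0.74.

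At 48 h TMT1A, a methyltransferase, had a log2 change of -4.51 (SE 0.35, limma with Benjamini-Hochberg, adjusted p = 0.000523). DEFB1, an antimicrobial peptide of tubule cells, had -4.50 (SE 0.50, adjusted p = 0.00111). The change was -3.58 (SE 0.48) in SLC2A2, a glucose transporter, -3.12 (SE 0.56) in CLDN2, a tight junction protein of the proximal tubule, and -3.26 (SE 0.42) in ELSPBP1. It was -3.33 (SE 0.81) in SUCNR1, the succinate receptor, -3.17 (SE 0.41) in ASB9, -3.14 (SE 0.78) in SLC44A5, -3.06 (SE 0.48) in SLC6A13, a GABA transporter, and -2.98 (SE 0.51) in SERPINF1, a secreted inhibitor of vessel growth. The probe sets used for TMT1A, SLC2A2, SLC44A5 and SUCNR1 were near background on all CsA arrays at 48 h, so their folds are uncertain in size. The same holds for DEFB1 and ELSPBP1, whose means over these arrays were 3.34 and 3.90, and a dimmer probe set of TMT1A had a log2 change of 0.07 (-2.22 for the mean of its probe sets).

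Among the rises at 48 h, RUNX2, a transcription factor of bone formation, changed by a log2 value of 2.68 (SE 0.82, limma adjusted p = 0.0488), ADORA2B, an adenosine receptor, by 2.47 (SE 0.41), PDE2A, a cyclic nucleotide phosphodiesterase, by 2.01 (SE 0.57), and DKK1, a secreted Wnt antagonist, by 1.88 (SE 0.25). TGFA, a ligand of the EGF receptor, rose by 1.72 (SE 0.25), CNIH3 by 1.74 (SE 0.18), ANKRD29 by 1.91 (SE 0.23), ERFE, a hormone that lowers hepcidin, by 1.91 (SE 0.48), MAP4K3-DT by 1.85 (SE 0.35) and ITPKA, an inositol phosphate kinase, by 1.84 (SE 0.36). A second probe set of ANKRD29 gave 0.28 (1.09 for their mean). The probe sets used for ANKRD29 and PDE2A were dim, with means of 4.85 and 5.35 over all arrays, so the sizes of these rises are uncertain. The calls of RUNX2 and PDE2A were lost in 10 and 9 of the 12 fits that left out 1 array. Those of SLC44A5 and SUCNR1 were lost in 3 and that of ERFE in 2. The value was 1.32 for PDE2A without CsA 48 h replicate 3 and 1.18 with array weights, and without control 48 h replicate 2 it was 1.59 for RUNX2 and 1.27 for ERFE.

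**Figure D2:**
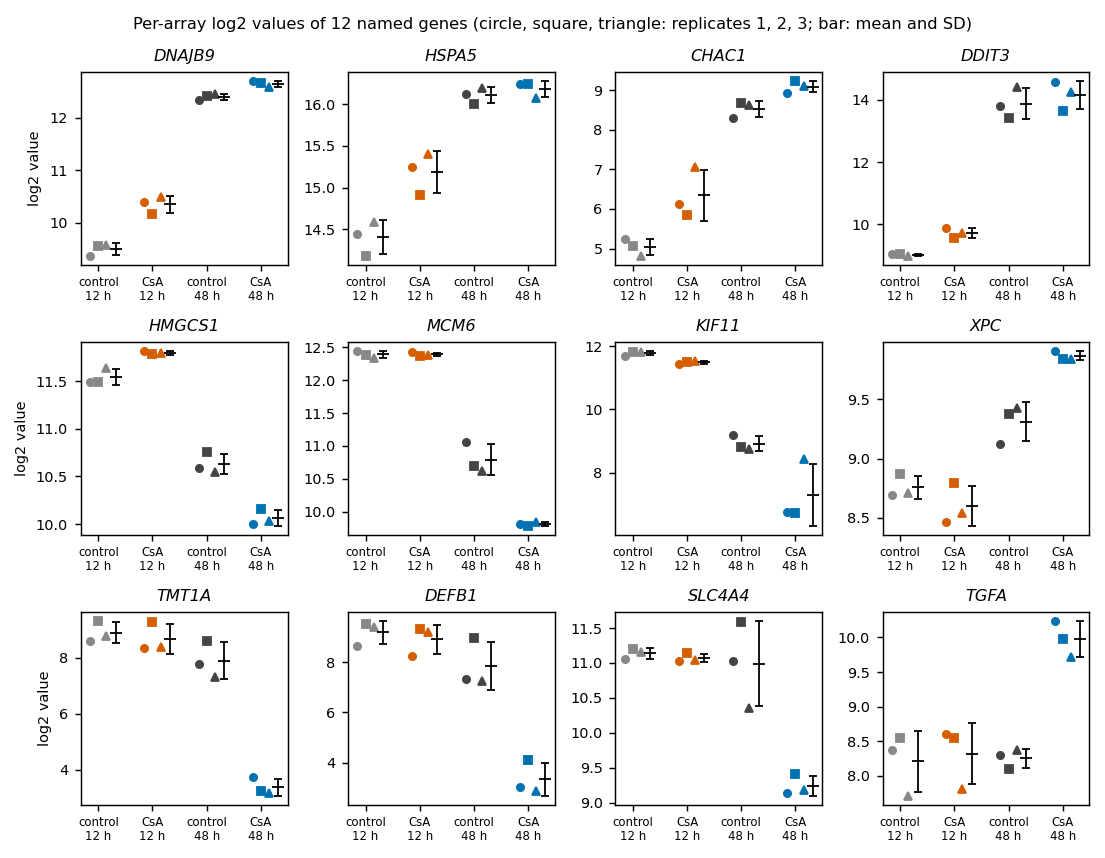
Log2 value of 12 named genes on each array, by group, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean and SD. DNAJB9 is higher with CsA at 12 h (log2 change 0.84), TMT1A, DEFB1, SLC4A4 and MCM6 are lower with CsA at 48 h (-4.51, -4.50, -1.75 and -0.98) and TGFA is higher (1.72).

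Among the lists at 48 h, DNA replication showed the lowest camera p. Its median was -0.74, and 18 of 39 members fell, or 21 when adjusted over the list alone (camera adjusted p = 2.03e-08, and adjusted p = 0.619 with an estimated correlation). The log2 change was -0.98 (SE 0.10) in MCM4, -0.98 (SE 0.11) in MCM6 and -0.74 (SE 0.09) in MCM7, all parts of the replicative helicase, and -1.55 (SE 0.23) in CCNE2, a cyclin of S phase entry. The mitosis list had a median of -0.61. Of its 33 members 1 fell, by both adjustments: KIF11, a spindle motor, with -1.61 (SE 0.37). The list had a camera adjusted p of 0.0211, and adjusted p = 0.855 with an estimated correlation. Replicate 3 of CsA at 48 h, the array with the low hybridization signal, moved with both lists. Its mean over the mitosis list was 10.10, against 8.12 and 7.52 in replicates 1 and 2 and 9.08 to 9.53 in the controls, and its mean over the DNA replication list was 9.00, against 8.31 and 8.23 and 9.01 to 9.45. Without it, 30 of 33 mitosis genes fell (median -1.47), and 28 of 39 DNA replication genes (median -0.93), against 10 and 7 in a fit of the remaining 48 h arrays alone. Array weights gave a mitosis median of -1.23. Without both 48 h replicate 1 arrays, those with low poly-A signals, the DNA replication median was -0.45 with 10 of 39 members falling, and the mitosis median -0.20 with the call lost (camera adjusted p = 0.5004).

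**Figure D3:**
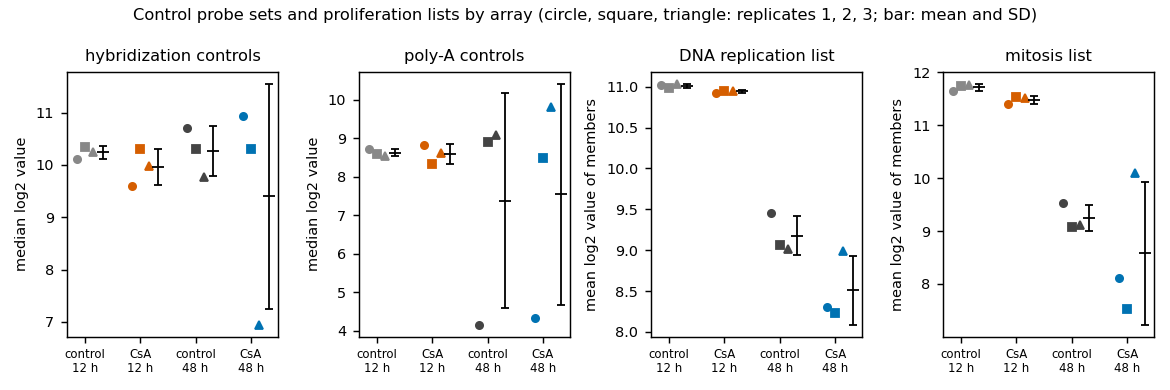
Median log2 signal of the hybridization and poly-A control probe sets and mean log2 value over the DNA replication and mitosis lists on each array, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean and SD. CsA 48 h replicate 3 has a hybridization signal of 6.95 and a mitosis mean of 10.10, above the controls of that time.

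Proximal tubule genes were lower at 48 h, with a median of -1.02 over the 9 measured members. Most genes of this list were not measured, because no probe set with 1 symbol passed the filter. Of these 4 fell over all genes and 6 when adjusted over the list alone (camera adjusted p = 0.00765, and adjusted p = 0.555 with an estimated correlation). SLC4A4, the basolateral sodium bicarbonate cotransporter, had -1.75 (SE 0.23) and CDH6, an adhesion molecule of the tubule, -1.16 (SE 0.10). Other probe sets of CDH6 gave -0.37 to -2.50, a wider range than its SE conveys. PDZK1, a scaffold of apical transporters, had -1.02 (SE 0.19) and CDH16, kidney cadherin, -0.95 (SE 0.17). With dim probe sets kept in the test, which adds members too dim for the filter, the list median was 0.01 and the call ended. Cholesterol synthesis and uptake had a median of -0.27 at 48 h, and 4 of 18 members fell, or 8 when adjusted over the list alone (camera adjusted p = 8.57e-04, and adjusted p = 0.555 with an estimated correlation). They were TM7SF2, a sterol reductase (-1.16, SE 0.20), HMGCS1, HMG-CoA synthase (-0.57, SE 0.08), IDI1, an isomerase of the pathway (-0.49, SE 0.08) and DHCR7, which makes cholesterol from its precursor (-0.42, SE 0.13). With the mean of all probe sets of a gene the calls of HMGCS1 (-0.86) and IDI1 (-0.25) ended, and DHCR7 lost its call in 9 of the 12 fits that left out 1 array. Oxidative phosphorylation had a median of -0.16 over 35 members, and 3 fell, also 3 when adjusted over the list alone (camera adjusted p = 0.00714, and adjusted p = 0.555 with an estimated correlation). They were ATP5MC1 (-0.52, SE 0.13), ATP5MC3 (-0.45, SE 0.12) and NDUFS3 (-0.31, SE 0.08).

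The lists shifted upward at 48 h were p53 targets, the ATF4 and CHOP response and the tRNA synthetases. The p53 targets had a median of 0.34, and 6 of 18 rose, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00661, and adjusted p = 0.555 with an estimated correlation). Among them PLK3 rose by 0.78 (SE 0.17), XPC, a DNA repair factor, by 0.55 (SE 0.11), PHLDA3 by 0.55 (SE 0.12) and TIGAR by 0.47 (SE 0.10). The p53 list mean of CsA 48 h replicate 3, 10.895, lay within the controls (10.747 to 10.904), against 11.197 and 11.183 in replicates 1 and 2. Without that array the list median was 0.42 with 8 members higher, or 1 in the remaining 48 h arrays alone. CDKN1A, the main cell cycle inhibitor among p53 targets, had 0.40 (SE 0.24, limma adjusted p = 0.288) and was looked up after the values were seen. The ATF4 and CHOP response had a median of 0.24. Of its 24 members 3 rose by both adjustments (camera adjusted p = 0.00765, and adjusted p = 0.555 with an estimated correlation). SLC3A2, an amino acid transporter subunit, rose by 0.76 (SE 0.12), GDF15 by 0.69 (SE 0.19; call lost in 5 of the 12 fits that left out 1 array) and CEBPG by 0.44 (SE 0.10; 0.29 with array weights). Of 15 tRNA synthetases, 4 rose (6 when adjusted over the list alone), with LARS1 at 0.65 (SE 0.13) and a list median of 0.15 (camera adjusted p = 0.0205, and adjusted p = 0.725 with an estimated correlation). Other probe sets of LARS1 gave 0.53, 0.18 and 0.11, and its call ended with their mean (0.37), without both 48 h replicate 1 arrays and in the fits of 48 h arrays alone (limma adjusted p up to 0.0906). The mean of all probe sets also ended the 48 h calls of PLK3 (0.66), PHLDA3 (0.47), RCAN1 (-0.64) and RUNX2 (2.68).

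Of the cyclophilin, calcineurin and marker genes named beforehand, 1 passed at 48 h. RCAN1 fell by 0.47 (SE 0.14, limma adjusted p = 0.0463), a call lost in 9 of the 12 fits that left out 1 array. PPIA had -0.14 (SE 0.07), PPIB 0.33 (SE 0.13), PPP3CA -0.25 (SE 0.15; -0.43 with limma adjusted p = 0.0257 without CsA replicate 3), HAVCR1 -0.17 (SE 0.21), HMOX1 -0.17 (SE 0.18), DDIT3 0.28 (SE 0.26) and HSPA5 0.08 (SE 0.14). The cyclophilin list had a median of 0.03 over 16 members with none passing over all genes or over the list alone (camera adjusted p = 0.844). The calcineurin and NFAT list had a median of 0.11 with 3 of 12 members higher and 2 lower, by both adjustments (camera adjusted p = 0.678). Markers of other kidney cell types were not called as lists in any CsA contrast. At 48 h they were fibroblast and mesangial (5 measured, camera adjusted p = 0.268), endothelial (2, 0.581), podocyte (5, 0.989), leukocyte (1, 0.492) and loop, distal tubule and collecting duct (5, 0.892). Within them COL1A1 (-0.95) and LUM (-1.68), both matrix genes, and AQP3, a water channel (-1.38), fell. COL1A1 also belongs to the matrix list. These 3 were also lower when adjusted over their list alone, as was 1 podocyte gene, with 1 podocyte gene higher.

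In all, 1795 of 11154 genes passed at 48 h in limma, 692 higher and 1103 lower, of which 80 higher and 236 lower were changed at least 2-fold. At an unadjusted p under 0.05 there were 3536, and 29.7% of genes had separated arrays, against 10% if all arrays were independent. A fit of the 48 h arrays alone, free of the tighter 12 h spread, called 123 genes, 31 higher and 92 lower, of which 122 were among the 1795. In simulated data with 200 changed genes, a mean of 80.5 of the shared fit's 242.9 calls at 48 h were false (33.1%). That share depends on how many genes change, so it is not an estimate for the 1795. Of the 20 genes with the largest changes, 8 passed in that narrower fit: TMT1A, DEFB1, SLC2A2, ELSPBP1, ANKRD29, CNIH3, DKK1 and TGFA. Of the members of the 8 lists called at 48 h, 3 DNA replication genes, 1 proximal tubule gene and 1 ATF4 and CHOP gene passed there, and of the cyclophilins, the calcineurin and NFAT list and the markers of other kidney cell types 0. Among other lists that camera did not call at 48 h, immediate early genes held 3 higher members in that fit. Fatty acid synthesis, lysosome and autophagy, and epithelial junctions and keratins held 1 lower member each. Leaving out CsA replicate 1, control replicate 1 or control replicate 2 gave 1011, 1099 and 731 calls, respectively. The mitosis list lost its call without CsA replicate 1 (median -0.36) or 2 (-0.13) or control replicate 1 (-0.49) or 3 (-0.69), the p53 targets without CsA replicate 1 (0.27) or 2 (0.21), and the tRNA synthetases without control replicate 2 (0.14; 0.23 without control replicate 3, where the call held).

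The change with CsA differed between the times for 125 genes in limma, with 25 more positive and 100 more negative at 48 h. Among the more negative differences were TMT1A (-4.30, SE 0.50, limma with Benjamini-Hochberg, adjusted p = 0.0163), DEFB1 (-4.23, SE 0.70), ELSPBP1 (-3.53, SE 0.59), ASB9 (-2.97, SE 0.58) and CILP, a matrix protein (-2.86, SE 0.52), all but ASB9 with a mean under 4 with CsA at 48 h, so that their sizes are uncertain. ELSPBP1, with a mean of 4.96 over all arrays, rose by 2.88 with time in controls. Its low level at 12 h left little room for a fall with CsA at that time. In the positive direction were CNIH3 (1.41, SE 0.26), PLCG2, a phospholipase (1.29, SE 0.24), UPP1, uridine phosphorylase (1.27, SE 0.25), SLCO4A1, an organic anion transporter (1.19, SE 0.22) and PHYKPL (1.16, SE 0.14). HMGCS1 had 0.26 at 12 h and -0.57 at 48 h, IDI1 0.22 and -0.49, and ELOVL6, a fatty acid elongase, 0.25 and -0.99, none passing at 12 h and all with passing differences (-0.82, -0.72 and -1.24). With the mean of all probe sets the differences of HMGCS1 (-1.17) and IDI1 (-0.25) did not pass, nor did those of MCM4 (-0.85), PHYKPL (1.11) and SC5D (-0.58), and TMT1A had -2.11. For IDI1, 2 dimmer probe sets had differences of 0.19 and 0.22.

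The list of cholesterol synthesis and uptake had a median difference of -0.52 with 3 of 18 members passing, and 11 when adjusted over the list alone (camera adjusted p = 1.98e-09, and adjusted p = 0.362 with an estimated correlation). Fatty acid synthesis had -0.51 with 1 member passing, and 4 over the list alone (camera adjusted p = 0.000316, and adjusted p = 0.417 with an estimated correlation). Proximal tubule had -0.99 with 2 passing, CDH6 (-1.25, SE 0.14) and SLC4A4 (-1.69, SE 0.33), and 4 over the list alone (camera adjusted p = 0.00117, and adjusted p = 0.417 with an estimated correlation), and with dim probe sets kept its median was 0.0037 and the call ended. Other probe sets of CDH6 had differences from -0.57 to -1.92. DNA replication had -0.63 (-0.42 without both 48 h replicate 1 arrays) with 2 passing, MCM6 (-0.98, SE 0.15) and MCM4 (-0.97, SE 0.14), and 12 over the list alone (camera adjusted p = 6.57e-08, and adjusted p = 0.614 with an estimated correlation). The ER chaperones had -0.33 with none passing over all genes, and 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.716 with an estimated correlation). NRF2 targets had -0.11 (-0.06 with dim probe sets kept) with AKR1C3 (-1.59, SE 0.32) and AKR1C2 (-1.12, SE 0.18), both aldo-keto reductases, passing, and 4 over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.510 with an estimated correlation). The p53 targets had 0.31 (camera adjusted p = 0.00287, and adjusted p = 0.510 with an estimated correlation) and ribosome biogenesis 0.14 (0.06 with array weights; camera adjusted p = 0.0256, and adjusted p = 0.716 with an estimated correlation), with no member of either passing over all genes and 4 and 0 when adjusted over the list alone.

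The count of 125 lay between 0 and 442 when 1 array was left out, every one of the 12 omissions moved it by more than 1.5 times, and each of the 20 named genes with a passing difference lost its call in 3 to 10 of these fits. In these fits the ER chaperone list lost its call without CsA 12 h replicate 3 (-0.23), CsA 48 h replicate 2 (-0.31) or 3 (-0.33), control 12 h replicate 2 (-0.33) or control 48 h replicate 3 (-0.20), p53 targets without CsA 48 h replicate 2 (0.24), and NRF2 targets and ribosome biogenesis in 6 and 4 of the 12, with medians of -0.20 to -0.06 and 0.07 to 0.17. Across genes the effects at 12 h and 48 h had a Pearson correlation of 0.24 and a Spearman correlation of 0.22, where genes are not independent replicates and no array is shared. The jackknife SD of the Pearson correlation over arrays was 0.137. It treated the 12 arrays as 1 set rather than 4 groups of 3, so it does not decide whether the correlation differs from 0. Of the genes called at 48 h, 68.0% had the same sign at 12 h. Of the 190 genes higher at 12 h at an unadjusted p under 0.05, 45 were called higher at 48 h, against 11.8 from independent lists, and of the 128 lower genes 37 were called lower, against 12.7. These expected counts treat genes as independent. Both effects also use the same estimate of each gene's spread, so genes with a small spread can pass at both times without a shared effect. Overlaps in opposite directions were not counted, so the excess does not show a shared effect.

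More genes passed for time in culture than for CsA. In controls, the rises between 12 h and 48 h included DDIT3, by a log2 value of 4.84 (SE 0.26, limma with Benjamini-Hochberg, adjusted p = 9.66e-07), ERO1B, an ER oxidoreductase, by 4.72 (SE 0.28), and INHBE, an activin subunit, by 5.06 (SE 0.30). BEX2 rose by 5.23 (SE 0.50) and TRIM22, an interferon-inducible gene near background at 12 h, by 4.89 (SE 0.40). The falls included NEIL3, a DNA glycosylase (-5.70, SE 0.78), NCAPH, a condensin subunit (-5.11, SE 0.72), ORC1, of the origin recognition complex (-4.57, SE 0.48), FAM111B (-4.54, SE 0.44) and ZBED2 (-4.38, SE 0.42). Sizes are uncertain for ERO1B, with a mean of 3.68 in controls at 12 h, and for FAM111B (3.28), ZBED2 (3.63), NCAPH (4.04) and NEIL3 (4.11) at 48 h, as for TRIM22.

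By list, 23 of 24 ATF4 and CHOP genes rose with time, also when adjusted over the list alone (median 2.11, camera adjusted p = 2.21e-15, and adjusted p = 0.0229 with an estimated correlation). So did 23 of 26 ER chaperones, or 24 over the list alone (median 1.73, camera adjusted p = 1.86e-13, and adjusted p = 0.199 with an estimated correlation). Of the p53 targets 16 of 18 rose and 1 fell, or 17 and 1 over the list alone (median 1.01, camera adjusted p = 5.65e-07, and adjusted p = 0.199 with an estimated correlation). Of the tRNA synthetases 11 of 15 rose and 1 fell by both adjustments (median 0.93, camera adjusted p = 4.81e-06, and adjusted p = 0.221 with an estimated correlation). DNA replication fell in 37 of 39 members by both adjustments (median -1.75, camera adjusted p = 1.53e-17, and adjusted p = 0.221 with an estimated correlation). Mitosis fell in 33 of 33 by both adjustments (median -2.47, camera adjusted p = 1.06e-11, and adjusted p = 0.405 with an estimated correlation). Cholesterol synthesis and uptake fell in 13 of 18 and rose in 3 by both adjustments (median -0.55, camera adjusted p = 0.00106, and adjusted p = 0.315 with an estimated correlation). In total 5077 genes passed in limma, 2746 higher and 2331 lower, and 60.2% of genes had separated arrays, against 10% if all arrays were independent, which the pairing of the controls breaks.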

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

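The tests of degraded RNA, of the position along the time course, of the larger 48 h spread and of slopes freed from noise were chosen after the results were seen, as were the compression put into replicate 3 and the omission of both 48 h replicate 1 arrays. How the hybridization, slope and covariance tests were read was also changed after their first values were known, as said beside each.

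The change with CsA differed between 12 h and 48 h by the test of the difference itself for 125 genes. Among named genes the difference was -4.30 for TMT1A, -4.23 for DEFB1, -3.53 for ELSPBP1, -2.97 for ASB9, -2.86 for CILP, -1.69 for SLC4A4, -1.59 for AKR1C3, -1.25 for CDH6, -1.24 for ELOVL6, -1.12 for AKR1C2, -0.98 for MCM6, -0.97 for MCM4, -0.82 for HMGCS1, -0.72 for IDI1 and -0.47 for SC5D. It was 1.16 for PHYKPL, 1.19 for SLCO4A1, 1.27 for UPP1, 1.29 for PLCG2 and 1.41 for CNIH3. By camera at the preset correlation, the median difference was -0.33 for ER chaperones, -0.11 for NRF2 targets, -0.52 for cholesterol synthesis and uptake, -0.51 for fatty acid synthesis, -0.63 for DNA replication, -0.99 for proximal tubule, 0.31 for p53 targets and 0.14 for ribosome biogenesis. With an estimated correlation 0 of these 8 lists were called (lowest adjusted p = 0.362). Of 3046 probe sets with no single gene name, 311 passed in limma with CsA at 48 h (2 higher and 5 lower in the 48 h arrays alone), 12 for the difference and 0 at 12 h.

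Other divisions of the arrays were fitted in the same way. With 3 against 3 there are only 10 divisions, too few for a share under 0.05. The real one called 1 gene at 12 h (the highest other 0), 1795 at 48 h (5) and 5077 for time in controls (0), and in each case 1 of the 10 divisions, the real one, gave that many. For the difference, 9 of 100 drawn divisions, the real one included, called at least 125 genes, with a highest of 821. All 9 kept the real division at 48 h, and the highest count among divisions that changed it was 1. Such divisions stand for no CsA effect at either time, not for equal effects at both. A 48 h effect set against a mixed 12 h division can itself give a difference. The 9 of 100 therefore cannot decide whether the count of 125 arose by chance.

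Replicate 3 of CsA at 48 h stood apart from replicates 1 and 2, with a hybridization control signal of 6.95 against 9.60 to 10.95 on the other arrays. Its poly-A control signal, 9.82, was the highest of the 12 arrays, as was its share of probe sets above a log2 value of 4 (42.8%). The low signal was therefore not shared by both kinds of control. A weaker hybridization that shifts dim against bright genes stays open: its deviation correlated with expression level at an absolute 0.0769, below the 0.136 of CsA 48 h replicate 2, but the bound set on this was wrong, because a compression put into the array gave a correlation of -0.894 before and -0.0392 after quantile normalization, which hides such a shift. A stronger response to CsA stays open too: its slope on the other replicates was at most 0.747, which the bound set beforehand would exclude, but replicates 1 and 2 also stayed below 1 (0.948 and 0.786), because noise in the predictor lowers every slope. Slopes freed from noise ran from 0.687 to 4.48 for replicate 1 (median 1.67), from 0.238 to 2.24 for replicate 2 (0.697) and from 0.223 to 1.51 for replicate 3 (0.837). Degraded RNA stays open too, since its difference between 3' and 5' ACTB probe sets, 1.22, lay below the 1.33 of control 48 h replicate 1 and above the median of 0.87, while its GAPDH difference, 0.143, was the highest of the 12 arrays (-0.112 to 0.0158 on the others). A culture at another stage of growth may account for the array and was not tested.

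The DNA replication list was lower with CsA at 48 h by camera at the preset correlation, though not with an estimated one (adjusted p = 0.619), and 3 of 39 members passed in the 48 h arrays alone. Replicate 3, with a list mean of 9.00 near the controls (9.01 to 9.45), opposed the shift seen in replicates 1 and 2 (8.31 and 8.23), so leaving it out could only lower the median (to -0.93), and without both 48 h replicate 1 arrays the median was -0.45 with 10 members falling. If the CsA cultures lay further along the change that controls show with time, as fewer dividing cells could, other genes would follow: the covariance of the CsA effect with the control time change over 11082 other genes was 0.0482, inside the range of simulations without a CsA effect (-0.18 to 0.0546), and with divided controls it was 0.0344 to 0.101. This met the bound written for excluding the explanation. The values, with shared or divided controls, lie below the 0.229 that would follow if those genes had moved as far along as the list. But the shared control arrays alone took the simulated covariance as low as -0.18, so 0.0482 cannot exclude a shift of that size. No simulated range was made for divided controls. The bound comes from simulations whose range depends on the random draws, so it was set aside. A shift along the time course or a direct effect of CsA on the cell cycle stays open.

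The ER chaperone list was shifted upward with CsA at 12 h by camera at the preset correlation (adjusted p = 0.0591 with an estimated correlation; 1 of 26 members passed), while at 48 h its median was 0.06. Saturation of bright probe sets could hide a late rise, but among the 15 members below a log2 level of 13 the median difference was -0.19 with a bootstrap interval of -0.40 to 0.10, which leaves it open. The wider spread at 48 h could hide a rise as well: the difference had adjusted p = 0.716 with an estimated correlation, and the mean difference over the list was -0.29 with an interval of -0.69 to 0.10. An early response that fades as controls reach the same level is a further hypothesis that these tests do not separate.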

How the results depend on the processing

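The fits that add the replicate block to the compared groups, block within each time, omit both 48 h replicate 1 arrays or omit CsA 48 h replicate 3 from the 48 h arrays were chosen after seeing the data. With dim probe sets kept, which adds members too dim for the filter, the proximal tubule median turned from -1.02 to 0.006 at 48 h and from -0.99 to 0.0037 for the difference. Signs also turned for genes that were not called. With 1 array left out, at 12 h PPIA ranged from -0.0694 to 0.0068 (turned without CsA replicate 1), RCAN1 from -0.1743 to 0.0437 (without control replicate 1) and HMOX1 from -0.0699 to 0.0639 (without CsA replicate 2 or control replicate 3), and at 48 h HAVCR1 from -0.3289 to 0.0887 (without CsA replicate 2) and HMOX1 from -0.3169 to 0.0893 (without CsA replicate 3, also in the 48 h arrays alone). HMOX1 at 48 h turned with array weights too (0.0887). No other named gene or list turned. For time in controls 4185 to 5919 genes passed with 1 array left out, and the count moved only when tested against a 1.2-fold change (2700). At 12 h, the 1 gene became 0 with the mean of probe sets, quantile normalization, cyclic loess, the 12 h arrays alone, the replicate block, the block within each time, the 1.2-fold test and without the 48 h replicate 1 arrays, 2 with dim probe sets kept, 2 (KLF4 and PTPRR, the latter chosen after its values were seen) with the 12 h arrays and the block, and 0 to 1 with 1 array left out. At 48 h, 1795 became 123 with the 48 h arrays alone, 24 with these and the block, 186 with these without CsA replicate 3, 480 without both replicate 1 arrays, 339 with the 1.2-fold test, 2981 with array weights and 731 to 2175 with 1 array left out. The difference, 125, became 49 with dim probe sets kept, 192 with trend and robust priors, 396 with the block, 370 with the block within each time, 1199 with array weights, 2 without the replicate 1 arrays, 0 with the 1.2-fold test and 0 to 442 with 1 array left out. Part of the change at 48 h follows from the spread shared with 12 h arrays and from fewer arrays; for the others the cause was not tested. The correlation of the effects at both times stayed at 0.138 to 0.290.

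With the block 2200 genes passed at 48 h, where same-numbered arrays correlated at 0.0963, 0.300 and -0.0506. CsA replicates 1 and 2 correlated best with the control of their own number (at most 0.0350 and 0.0407 with others), but replicate 3 did not (0.206). Both 48 h replicate 1 arrays also had low poly-A signals, so whether numbers pair the 48 h arrays stays open. Beyond the counts given and DNAJB9, the block across all 12 arrays ended no call of a named gene or list, while 2 named genes at 48 h, PPIB among them (adjusted p = 0.0368), and 7 for the difference newly passed. Of the lists, quantile normalization and both other fits with the block ended the 12 h call of oxidative phosphorylation, and a filter at a log2 value of 6 that of NF-kB targets. For the difference, the block within each time and array weights ended the calls of ER chaperones and NRF2 targets, cyclic loess and the higher filter that of NRF2 targets, and keeping dim probe sets that of proximal tubule. At 48 h array weights (median -0.93), dim probe sets kept (0.01) and the 48 h arrays without CsA replicate 3 (-0.83) ended that of proximal tubule. Without both replicate 1 arrays 4 of 8 lists kept their call at 48 h. Of 48 called named genes at 48 h, 3 kept the call in all 25 alternatives, and of 10 for time, 10 did. With the mean of probe sets 40 of the 48 stayed called, and 15 of 20 for the difference. PPP3CA at 48 h also passed with array weights (-0.51). At 48 h 944 genes were higher and 1054 lower with quantile normalization, and 917 and 1034 with cyclic loess. Signal over background limits dim genes. Without the filter 19775 genes were tested, and 38 of the 48 stayed called, and 9 of 20 for the difference. The adjustment then ran over more genes, so these losses do not show that low signal limits the named genes. By fry, 0 of 9 lists at 12 h, 6 of 8 at 48 h and 3 of 8 for the difference kept their call. Neither fry nor camera with an estimated correlation was run with the replicate number as a block, so neither used the pairing at 12 h. The means of these 9 lists at 12 h shifted the same way at each replicate number, though the lists were called from the same arrays.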

Other observations

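Except HMOX1, AKR1C3 and AKR1C2, the genes named here were chosen after their values were seen, from lists fixed beforehand that camera did not call at 48 h. Of the lists in these first 2 paragraphs, NRF2 targets held 2 lower members in a fit of the 48 h arrays alone, xenobiotic metabolism 1 lower and the matrix list 1 higher, and the others 0. With CsA at 48 h the aldo-keto reductases AKR1C3, AKR1C2 and AKR1C1 had log2 changes of -1.70 (SE 0.22; limma adjusted p = 0.00162), -1.26 (SE 0.13) and -1.09, while HMOX1 did not pass. The 3 are closely related in sequence, so their probe sets can share signal. Of 20 NRF2 targets 4 were lower over all genes, and 4 lower and 1 higher over the list alone (median -0.13; camera adjusted p = 0.0633). CYP1B1 and TIPARP, both targets of the aryl hydrocarbon receptor, were lower by -1.21 and -0.97 in the list of xenobiotic metabolism and efflux, where 2 of 12 members passed by both adjustments (camera adjusted p = 0.230). Interferon-stimulated genes went both ways, with IFI44 at -1.47, IFIT1 at -1.25 and RIGI at -0.65 lower, and MX1 at 0.77 higher. Of 17 members 2 were higher and 5 lower (3 and 6 when adjusted over the list alone; camera adjusted p = 0.492).

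Tubular injury genes were also mixed at 48 h. In that list VCAM1, an adhesion molecule, had -2.53 and CLU, clusterin, -0.59, while KRT7, a keratin, had 1.13 and SOX9, a regulator of tubule repair, 0.62; 3 of 17 members were higher and 4 lower (4 and 4 when adjusted over the list alone; camera adjusted p = 0.989). Of 26 hypoxia and glycolysis genes 5 were higher and none lower by both adjustments (median -0.03; camera adjusted p = 0.492), among them SLC2A1, a glucose transporter, at 1.28, NDRG1 at 0.91 and VEGFA, a growth factor for vessels, at 0.82. SNAI2, a transcription factor of mesenchymal cells, rose by 1.62, while the matrix genes COL1A1 (-0.95), LOXL2 (-0.53) and SPARC (-0.35) were lower. The list of extracellular matrix and TGF-beta targets held 1 higher and 3 lower of 18 members (2 and 4 when adjusted over the list alone; camera adjusted p = 0.492). The ER chaperone list held 2 higher members at 48 h, SELENOS at 0.85 and EDEM2 at 0.78, by both adjustments (camera adjusted p = 0.134).

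Over time in controls, further lists were called by camera at the preset correlation, in tests added after the data had been examined. Heat shock genes fell in 12 of 16 members by both adjustments (median -0.43; camera adjusted p = 2.83e-05; adjusted p = 0.146 with an estimated correlation), and oxidative phosphorylation in 12 of 35 with 1 rising (median -0.13; camera adjusted p = 0.00500; adjusted p = 0.289 with an estimated correlation). Of the lysosome and autophagy genes 15 of 28 rose and 1 fell (15 and 3 when adjusted over the list alone; median 0.36; camera adjusted p = 0.0237; adjusted p = 0.208 with an estimated correlation).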
